A study of Arabidopsis thaliana with 9 samples.

How the data were processed

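RNA sequencing was compared between Arabidopsis thaliana Col-0 wild type (WT) and the T-DNA insertion lines hac1-1 and hac1-2, with 3 libraries per genotype. Per the labels, full leaves 12 to 14 were collected at day 49 after sowing from plants grown under 20 h light and 4 h dark at 28 µmol photons per square metre and second, and total RNA was made into libraries by breath adapter directional sequencing. WT leaves are labelled senescent and mutant leaves non-senescent. The chromatin immunoprecipitation data named in the title were not analysed here.

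The authors deposited raw read counts for 33323 genes, made against genome build TAIR 10, with 10578 genes at 0 in all libraries. The aligner, the counting program, the counting strand and the annotation version were not given in the sources used here. The authors also deposited FPKM values for 18168 genes, which equal the count divided by the library total and by a gene length that was whole in 100% of genes within a tolerance of 0.001. Every gene in the FPKM table reached an FPKM of at least 1.0001 in some library. The count table held 0 plastid or mitochondrial genes. Coordinates came from the TAIR10.1 reference, in which 32835 of the gene identifiers were found.

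Library totals were 7350344, 5847562 and 8549215 counts for WT replicates 1 to 3, 7329298, 6651516 and 5750097 for hac1-1, and 7133722, 9461600 and 7117392 for hac1-2. A limit of 3 counts corresponds to 0.317 to 0.522 CPM, for counting error only, since reads are not independent molecules. The 18S ribosomal RNA genes took 12.1 to 21.0% of the counts.

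Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with a minimum count of 10 kept 16560 genes, TMM factors scaled the libraries, and quasi-likelihood tests compared hac1-1 with WT, hac1-2 with WT, hac1-2 with hac1-1, and the mean of both mutants with WT. All 9 libraries shared the dispersion estimate, with a biological coefficient of variation of 13.7%. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Genes counted as changed in both mutants had to be called in each with the same sign. CPM values use TMM-scaled library sizes. In the edgeR tests, 4095, 3680, 2376 and 4209 genes had an unadjusted p under 0.05 in the 4 comparisons, in the order given.

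There were 25 gene lists, written from general knowledge before the data were examined, as were the comparisons and their tests of genes and lists: senescence-associated genes, senescence NAC and WRKY factors, chlorophyll breakdown, chlorophyll synthesis, photosystems and light harvesting, Calvin cycle, salicylic acid and defence, jasmonate, ethylene, AP2/ERF stress factors, abscisic acid, cytokinin, nitrogen and phosphate remobilisation, autophagy, histone acetyltransferases, histone deacetylases, flowering, anthocyanin and flavonoid synthesis, circadian clock, touch and wound response, and markers of guard cells and trichomes, epidermis, phloem and xylem, and meristem and floral organs. The 24 lists with a measured member were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over all lists and both mutant comparisons, and separately for hac1-2 against hac1-1. Camera with an estimated correlation and fry were run beside it. Fry tests whether a list moves in 1 direction and does not compare it with other genes.

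Genes were named by a rule fixed before the data were examined. It named HAC1 and the measured histone acetyltransferases, ERF022, the 12 largest rises and the 12 largest falls shared by both mutants, up to 4 members per list with the smallest larger adjusted p, the 4 largest rises and falls in each mutant, the 6 largest rises and falls between the mutants, and the 3 genes with the most counts. The rankings by size of change used called genes with a mean of at least 5 CPM and no overlap between groups. ERF022, also a member of the AP2/ERF list, was named because a known study of these mutants is about it. Its choice was therefore not independent of that study. Other genes are named only where the text says that they were chosen after their values were seen.

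The overlap of the mutant comparisons was set beside 100 simulations in which unchanged groups were drawn against the WT libraries. On simulated data with 50 genes changed at each size, edgeR recovered 42% of genes changed 1.5-fold, 68 and 78% of those changed 2-fold and 96% of those changed 4-fold in hac1-1 and hac1-2, and 7.41 and 6.63% of the calls were false. On the same simulated libraries, for hac1-1 against WT alone, camera called 2 of 2 changed lists and 0 of 20 unchanged lists. Genes were drawn independently there and the unchanged lists held random genes. This cannot show how camera with the preset correlation behaves on lists of correlated genes. Near-identical copies of 486 genes were searched with BLAST 2.17.0, and 15 had a counted copy of at least 95% identity over at least 50% of their length. Figures were drawn with matplotlib 3.10.9.

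Alternatives were RLE, upper-quartile and library-size scaling, DESeq2 1.42.0, limma-voom, no filter, a stricter filter, only the groups compared, the replicate number as a block, an adjusted p under 0.01, a 2-fold minimum, FPKM values with pseudocounts of 1 and 0.1 or a mean FPKM of at least 1, and leaving out each library in turn.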

Results

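Full leaves 12 to 14 of Arabidopsis thaliana were sampled at day 49 after sowing, and the RNA of wild type Col-0 (WT) was compared with that of plants carrying an insertion in HAC1. HAC1 encodes a histone acetyltransferase of the CBP family, an enzyme class that adds acetyl groups to histones and acts as a transcriptional coactivator. The insertion lines were hac1-1 and hac1-2, each with 3 libraries, set against 3 WT libraries. According to the labels, WT leaves were senescent at this age and mutant leaves were not, so genotype and senescence state cannot be separated in these samples. The stated aim was to find potential targets of HAC1. Library totals ran from 5750097 to 9461600 counts, and 16560 genes had enough counts to be tested. The design names 1 biological replicate, so the p-values measure only the spread between these samples, which may be technical. Log2 CPM of replicate libraries correlated across genes at 0.963 to 0.980, and that of WT and mutant libraries at 0.941 to 0.959, where genes are not independent replicates. Along the leading principal component, which held 34.7% of the variance, all 3 WT libraries lay apart from all 6 mutant libraries. The next component separated hac1-1 from hac1-2.

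HAC1 transcript counts were reduced in hac1-1 but not detectably in hac1-2. The gene (AT1G79000) lies on chromosome 1 from 29716350 to 29724748 on the minus strand, in coordinates of the TAIR10.1 reference. WT libraries held 153, 167 and 147 CPM, hac1-1 libraries 58.6, 72.7 and 64.1 CPM, and hac1-2 libraries 151, 133 and 122 CPM. In hac1-1 HAC1 fell by 1.26 on the log2 scale (SE 0.12, edgeR adjusted p = 1.2e-08), to a level 2.39-fold lower than WT. In hac1-2 the log2 fold change was -0.20 (SE 0.11, edgeR adjusted p = 0.31). The level in hac1-2 was 2.07-fold that in hac1-1 (edgeR adjusted p = 3.3e-06). A count over the whole gene can include transcripts that run into or past an insertion, and the insertion sites were not used here. The HAC1 counts therefore check the hac1-1 labels and leave the hac1-2 labels unchecked, so every direction given for hac1-2 rests on its labels.

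None of the other 9 measured histone acetyltransferase genes was called lower in either mutant. HAC12, the closest relative of HAC1, stood at 76.5 ± 5.34 CPM in WT, 97.0 ± 5.84 in hac1-1 and 76.8 ± 2.92 in hac1-2 (SD, n = 3). It rose 1.27-fold in hac1-1 (edgeR adjusted p = 0.039), a call lost without any of the 3 hac1-1 libraries, without WT replicate 1 or 3, without a filter, with only the 2 groups compared and on FPKM values. The largest adjusted p over all alternatives was 0.187. Of the 10 measured list members, 1 rose and 1 fell in hac1-1, with the same counts adjusted over the list alone, and none was called in hac1-2. The camera test of the list gave adjusted p = 0.41 in hac1-1 and 0.84 in hac1-2, where its median (-0.02) and mean (0.03) differed in sign. HAC5 (46.1, 54.6 and 54.2 CPM in WT, hac1-1 and hac1-2), HAF1 (142, 163 and 135 CPM) and HAM2 (15.9, 20.2 and 22.7 CPM) did not pass the test. Histone deacetylase genes did not differ from other genes in the camera test, with 0 of 14 measured members called in either mutant, also when adjusted over the list alone (camera adjusted p = 0.31 and 0.32). In the fry test, which does not compare with other genes, they were higher in hac1-1 (adjusted p = 0.0448).

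**Figure D1:**
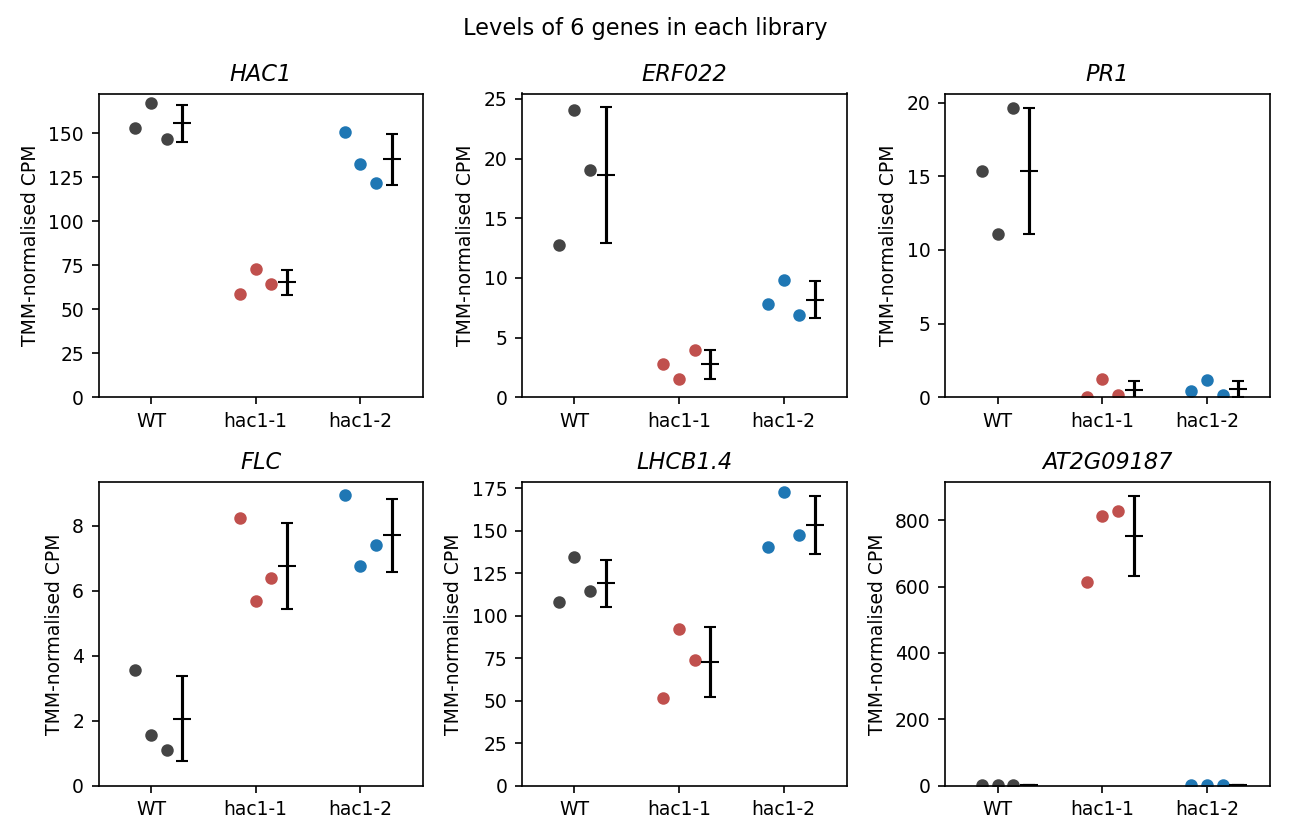
TMM-normalised CPM (vertical axes, starting at 0) of 6 genes in the WT, hac1-1 and hac1-2 libraries (horizontal axes); each point is 1 library, and the black bar with whiskers is the mean ± SD of 3 libraries. HAC1 lay at 58.6 to 72.7 CPM in hac1-1 and at or above 122 CPM in the other libraries, PR1 and ERF022 were lower in both mutants, FLC was higher in both, and AT2G09187 was high in hac1-1 alone of these 3 genotypes.

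In hac1-1 leaves, transcripts of defence, jasmonate, touch-response and senescence genes were lower than in WT, and transcripts of abscisic acid response genes were higher as a list. PR1, a marker of salicylic acid signalling, stood at 15.4 ± 4.27 CPM in WT and 0.467 ± 0.664 CPM in hac1-1 (SD, n = 3). PR1 in hac1-1 lay near the limit that 3 counts set, and its log2 fold change ran from -7.38 to -3.78 over the alternatives. The jasmonate-oxidising enzyme gene CYP94B3 fell 4.39-fold and the touch gene TCH3 2.53-fold, whereas RD29A, a dehydration and cold-response gene, rose from 1351 ± 39.4 to 3105 ± 396 CPM. ERF022, an AP2/ERF transcription factor gene, fell 6.74-fold, from 18.6 ± 5.68 to 2.77 ± 1.22 CPM. Across all genes, edgeR called 2092 of 16560 at an adjusted p under 0.05, 582 higher and 1510 lower, of which 129 and 629 changed at least 2-fold. Among genes called in hac1-1 without overlap between groups, the largest rise was that of AT2G09187, annotated as a pseudogene on chromosome 2 from 3639603 to 3646073 on the minus strand, from 1.95 ± 0.459 to 751 ± 120 CPM. BGAL11, a beta-galactosidase gene, fell to 1.51 ± 0.954 CPM, AIG1 fell by 3.80 on the log2 scale and BCP1 fell from 11.9 to 1.13 CPM, all past the edgeR threshold.

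Senescence-associated genes were lower as a list in hac1-1, while the senescence NAC and WRKY factors went both ways. Of 16 measured senescence-associated genes, 8 fell and 2 rose (9 and 2 adjusted over the list alone), with a median log2 fold change of -0.73 (camera adjusted p = 5.3e-06). SAG20 fell 3.06-fold, SEN1 2.66-fold, SAG14 2.37-fold and DIN10 2.24-fold, and SAG13 fell from 16.1 to 2.11 CPM. SAG12, often used as a marker of senescence, had 6 counts in the 3 WT libraries, 5 in hac1-1 and 0 in hac1-2. It was not tested, where 3 counts correspond to 0.317 to 0.522 CPM per library. Also untested were SWEET15 (7, 1 and 21 counts in WT, hac1-1 and hac1-2), DIN9 (10, 0 and 23), FRK1 (10, 19 and 11), BFN1 (9, 3 and 8) and DIN11 (2, 0 and 2). The 2 called members that rose were PAP17, an acid phosphatase gene (20.5 to 36.3 CPM), and SAG113, a protein phosphatase gene of abscisic acid signalling (34.6 to 72.1 CPM). These 2 and the untested members were chosen after their values were seen. Among 10 measured senescence WRKY factors, 4 fell and 3 rose, in the same numbers adjusted over the list alone, and 1 rose without WT replicate 3. WRKY53, a regulator of age-dependent senescence, fell 2.25-fold and WRKY22 2.49-fold. The list call (camera adjusted p = 0.032) was lost with an estimated correlation (adjusted p = 0.238) and without hac1-1 replicate 2 (0.119). Of 18 NAC factors, 5 fell and 2 rose (6 and 2 adjusted over the list alone), without a list call (camera adjusted p = 0.14). NAC019 fell 1.37-fold and RD26, a NAC gene of abscisic acid and drought response, rose (164.7 to 214 CPM), the latter call lost without WT replicate 1. The count of called NAC genes dropped to 4 without any of hac1-1 replicates 1 and 3 or WT replicate 1, and to 3 without WT replicate 3.

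The salicylic acid, jasmonate, AP2/ERF and touch lists fell in hac1-1. Of 20 measured salicylic acid and defence genes, 11 fell and 1 rose (12 and 1 adjusted over the list alone; camera adjusted p = 3.3e-06). PR2 fell 3.68-fold, PR5 5.81-fold and PBS3, an enzyme gene of salicylic acid synthesis, 2.84-fold. NIMIN1, which encodes a partner of the salicylic acid receptor NPR1, rose from 1.79 to 6.18 CPM and was chosen after its values were seen. This rise was not called without hac1-1 replicate 1, WT replicate 1 or WT replicate 2. Among 28 measured jasmonate genes, 16 fell and 2 rose (16 and 3 adjusted over the list alone; camera adjusted p = 1.2e-10), and 1 rose without hac1-1 replicate 1 or 3 or WT replicate 2 or 3. The repressor genes JAZ5, JAZ1 and JAZ9 fell 3.24-fold, 2.07-fold and 1.95-fold. AP2/ERF stress factors fell in 17 of 21 measured members, and 18 fell adjusted over the list alone (camera adjusted p = 7.9e-17). DDF1 fell 4.42-fold, and ERF5 and ERF6 fell from 678 to 295 and from 309 to 134 CPM. Rapid touch and wound response genes fell in 20 of 22 members, and all 22 fell adjusted over the list alone (camera adjusted p = 7.4e-32). This list shares members, among them JAZ1 and JAZ5, with the jasmonate and AP2/ERF lists. MYB15 fell 6.21-fold and the calmodulin-like gene CML37 2.26-fold.

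Abscisic acid response genes ran the other way in hac1-1. Of 23 measured members, 10 rose and 2 fell (10 and 3 adjusted over the list alone; camera adjusted p = 1.5e-06), with a median of 0.22. After RD29A, KIN1 rose 2.42-fold, RD22 1.72-fold and COR15A 1.62-fold. Ethylene genes had 2 risers and 2 fallers among 14, also adjusted over the list alone, and no list call (camera adjusted p = 0.65), and their median (0.06) and mean (-0.01) differed in sign. The EIN3-degrading F-box gene EBF2 rose 1.54-fold and the ethylene synthesis gene ACS6 fell 1.98-fold. Cytokinin response genes fell in 3 of 11 members, and 4 fell adjusted over the list alone. This call (camera adjusted p = 0.011) was lost with an estimated correlation (adjusted p = 0.0910). IPT3, a cytokinin synthesis gene, fell 2.71-fold and CKX4, a cytokinin oxidase gene, fell from 4.41 to 0.786 CPM.

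Calvin cycle transcripts in hac1-1 were lower than in WT, and photosystem transcripts were lower with the preset but not with an estimated correlation. Calvin cycle genes fell in 11 of 19 members, also adjusted over the list alone, with a median of -0.43 (camera adjusted p = 2.1e-07). RBCS1A, a small subunit of Rubisco, fell 1.37-fold, RBCS2B 2.39-fold and CP12-2 1.57-fold. Photosystem and light-harvesting genes fell in 7 of 42 members, and 14 fell adjusted over the list alone, with a median of -0.21 (camera adjusted p = 5.8e-07). That call was lost with an estimated correlation (adjusted p = 0.117), and without hac1-1 replicate 2, the library with the largest ribosomal RNA share (21.0%), the count of fallers was 13. Within the list LHCB1.4 fell 1.64-fold. Chlorophyll synthesis genes had 2 fallers of 16 (4 fallers and 3 risers adjusted over the list alone; camera adjusted p = 0.55), and 1 faller without hac1-1 replicate 2 or 3, WT replicate 1 or 3 or any hac1-2 library. Chlorophyll breakdown genes had 2 fallers of 14, also adjusted over the list alone. These were CLH1, a chlorophyllase gene, which fell 3.45-fold, and CV, a gene for chloroplast protein turnover, which fell 1.81-fold. The breakdown list as a whole was not called (camera adjusted p = 0.41), and its median (0.04) and mean (-0.16) differed in sign.

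Nutrient remobilisation genes fell in part in hac1-1. Of 15 measured nitrogen and phosphate remobilisation genes, 6 fell (8 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0015), and 3 fell without WT replicate 3. ASN1, an asparagine synthetase gene, fell 2.42-fold, the nitrate transporter gene NRT1.5 2.31-fold and the glutamine synthetase gene GLN1;4 1.99-fold. Among 7 measured members of the phloem and xylem list, all phloem genes, 2 fell (3 adjusted over the list alone), with SUC2, the sucrose loader of the phloem, 1.55-fold lower. This call (camera adjusted p = 0.0053) was lost with an estimated correlation (adjusted p = 0.0661). With an estimated correlation, hac1-1 kept the calls of the senescence-associated, salicylic acid, jasmonate, AP2/ERF, touch, abscisic acid, Calvin cycle and remobilisation lists, the largest adjusted p among them being 0.0400.

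In hac1-2 leaves, transcripts of defence, senescence, jasmonate and touch-response genes were again lower than in WT, while chlorophyll synthesis transcripts were higher. Light-harvesting transcripts were higher in the list test with the preset correlation, but not with an estimated correlation (adjusted p = 0.0527). PR1 stood at 0.571 ± 0.533 CPM against 15.4 ± 4.27 CPM in WT (SD, n = 3), near the limit that 3 counts set, and its log2 fold change ran from -5.73 to -3.59 over the alternatives. PR5 fell 6.71-fold, SAG20 2.61-fold and CYP94B3 2.22-fold. LHCB1.3, an abundant light-harvesting chlorophyll-binding protein gene, rose from 5362 ± 476 to 7664 ± 118 CPM, although LHCB1.1, LHCB1.2 and LHCB1.3 share at least 95% of their exonic sequence over parts of their length and their counts are uncertain. ERF022 fell 2.25-fold, to 8.19 ± 1.52 CPM (edgeR adjusted p = 0.0027), a call lost on log2(FPKM + 0.1) values (adjusted p = 0.0630). In this line edgeR called 1704 of 16560 genes at an adjusted p under 0.05, 472 higher and 1232 lower, of which 88 and 501 changed at least 2-fold. The share of called genes that were lower was 72.3%, 57.8% with library size as the only scaling and 62.0% on log2(FPKM + 1) values of genes with a mean FPKM of at least 1. Large falls were those of AT4G01390, a TRAF-like protein gene, from 15.4 ± 3.29 to 0.398 ± 0.253 CPM, and AIG1, which fell by 3.52 on the log2 scale. Among genes with a mean of at least 5 CPM over all libraries, the largest rise was that of AT5G35935, annotated as a pseudogene, from 0.747 ± 0.414 to 10.7 ± 0.939 CPM. This gene was called higher in hac1-1 too, with log2 fold changes of 3.705 in hac1-1 and 3.873 in hac1-2. The lowest values over the alternatives were 1.15 and 1.27.

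Senescence and defence lists fell in hac1-2 as well. Senescence-associated genes fell in 7 of 16 members, and 9 fell adjusted over the list alone, with a median of -0.73 (camera adjusted p = 7.5e-09). SEN1 fell 2.96-fold, DIN10 2.12-fold and SAG14 1.72-fold. WRKY factors fell in 5 of 10 members and NAC factors in 5 of 18, where 1 rose (6 WRKY, and 6 lower and 1 higher NAC genes, adjusted over the list alone). WRKY53 fell 1.68-fold, WRKY45 2.07-fold and NAC019 1.38-fold, and RD26 rose 1.35-fold. The count of NAC genes that fell was 3 without hac1-2 replicate 2, WT replicate 1 or WT replicate 3. Both calls (camera adjusted p = 4.2e-05 and 0.0081) were lost with an estimated correlation (adjusted p = 0.0659 for WRKY and 0.0661 for NAC). Salicylic acid and defence genes fell in 14 of 20 members, also adjusted over the list alone, with a median of -1.28 (camera adjusted p = 1.5e-11). PR2 fell 3.19-fold and PBS3 2.91-fold. Chlorophyll breakdown genes fell in 6 of 14 members (6 fell and 1 rose adjusted over the list alone), with CV 2.33-fold and CLH1 2.54-fold lower, and MES16 lower at 15.1 against 25.6 CPM. The breakdown call (camera adjusted p = 0.0040) was lost with an estimated correlation (adjusted p = 0.160).

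Jasmonate genes fell in 14 of 28 members in hac1-2 (16 fell and 3 rose adjusted over the list alone; camera adjusted p = 3.6e-09), and 1 rose without hac1-1 replicate 2, hac1-2 replicate 2, WT replicate 1 or WT replicate 2. JAZ5 fell 2.67-fold, JAZ9 1.86-fold and JAZ1 1.79-fold. AP2/ERF stress factors fell in 12 of 21 members and rose in 2 (15 and 2 adjusted over the list alone; camera adjusted p = 4.0e-09). DDF1 fell 1.69-fold and ERF6 1.73-fold. The 2 that rose were the cold-response regulators CBF1 (62.1 to 88.2 CPM) and CBF3 (45.2 to 59.7 CPM), chosen after their values were seen. Neither rise was called without hac1-2 replicate 3, and only 1 AP2/ERF gene rose without hac1-2 replicate 2, WT replicate 1 or WT replicate 3. Touch and wound genes fell in 14 of 22 members, and 19 fell adjusted over the list alone (camera adjusted p = 1.8e-22), with MYB15 7.97-fold, TCH3 2.13-fold and CML37 1.91-fold lower. Ethylene genes had 2 risers and 3 fallers of 14 (2 and 4 adjusted over the list alone; camera adjusted p = 0.55), with a median (0.03) and mean (-0.15) of different sign, and without hac1-2 replicate 2 there were 1 riser and 2 fallers. There was also 1 ethylene riser without hac1-2 replicate 1 or 3 or WT replicate 1 or 3. Abscisic acid genes rose in 5 of 23 members and fell in 2, also adjusted over the list alone, with RD29A at 2969 ± 43.7 CPM and KIN1 3.19-fold higher than WT. Their list call (camera adjusted p = 0.016) was lost with an estimated correlation (adjusted p = 0.104), without hac1-2 replicate 2 (0.0638) and on log2(FPKM + 1) values (0.0628). Cytokinin response genes had 2 fallers of 11, also adjusted over the list alone (camera adjusted p = 0.23), and CRF6 fell 2.21-fold. Without any of the 3 hac1-2 libraries or WT replicate 2 the cytokinin count was 1.

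Photosynthesis transcripts in hac1-2 were level with or above WT. Photosystem and light-harvesting genes rose in 12 of 42 members, and 18 rose adjusted over the list alone, with a median of 0.25 (camera adjusted p = 3.0e-12). This call was lost with an estimated correlation (adjusted p = 0.0527), and the count of risers was 7 without hac1-2 replicate 2, 6 without hac1-2 replicate 3, 5 without WT replicate 1 and 7 without WT replicate 3. Chlorophyll synthesis genes rose in 6 of 16 members, and 7 rose adjusted over the list alone (camera adjusted p = 6.7e-05). Of these, CHLI1, a subunit of magnesium chelatase, rose 1.47-fold and DVR 2.64-fold. The call of DVR was lost without WT replicate 3, and 3 synthesis genes rose without hac1-2 replicate 3 or without WT replicate 3. Calvin cycle genes had 1 riser of 19, also adjusted over the list alone (camera adjusted p = 0.64), and their median (-0.06) and mean (0.00) differed in sign. Remobilisation genes fell in 5 of 15 members, and 6 fell adjusted over the list alone (camera adjusted p = 0.0014), with ASN1 3.24-fold and NRT1.5 2.72-fold lower. Without hac1-2 replicate 1, WT replicate 2 or WT replicate 3 this count was 3. With an estimated correlation, hac1-2 kept the calls of the senescence-associated, salicylic acid, jasmonate, AP2/ERF, touch, remobilisation, chlorophyll synthesis and phloem and xylem lists, the largest adjusted p among them being 0.0424.

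Measured phloem markers were lower as a list in hac1-2, and in hac1-1 with the preset but not with an estimated correlation, and markers of other cell types were measured by few genes. In the phloem and xylem list, all 7 measured members are phloem genes, and 3 of them fell in hac1-2, and 5 fell adjusted over the list alone (camera adjusted p = 0.00046), with SUC2 1.54-fold and SWEET11 1.62-fold lower. The 5 xylem members had too few counts to be tested, and each had more counts in hac1-2 than in WT. Of these, IRX3 had 4 counts in WT, 11 in hac1-1 and 30 in hac1-2, chosen after its values were seen. Epidermis markers rose in 1 of 4 members in each mutant (1 in hac1-1 and 2 in hac1-2 adjusted over the list alone). This was LTP1, a lipid transfer protein gene, 1.72-fold and 2.11-fold higher. The epidermis call in hac1-2 (camera adjusted p = 0.0040) was lost with an estimated correlation (adjusted p = 0.0875), and in hac1-1 the list (camera adjusted p = 0.057) passed without WT replicate 1 (0.0493) and in the fry test (adjusted p = 0.0183). Of 6 measured guard cell and trichome markers 0 changed in hac1-1 and 2 fell in hac1-2, FAMA and MYB60, with the same counts adjusted over the list alone. That list was not called (camera adjusted p = 0.23 and 0.095), and on log2(FPKM + 1) values it passed in hac1-2 (0.0479). In the fry test it was lower in both mutants (adjusted p = 0.011 in hac1-1 and 0.0034 in hac1-2). The call of FAMA was lost without WT replicate 2 or hac1-2 replicate 3 and on FPKM values, and that of MYB60 without WT replicate 3. WRKY53, DIN10, ASN1, NRT1.5, EBF2, CHLI1, LHCB1.3, HAF1, ICS2 and AT4G01390 overlap a counted gene on the other strand, and the counting strand was not given in the sources used here. None of 6 meristem and floral organ markers had enough counts to be tested.

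Autophagy genes had 0 of 26 members called in hac1-1 and 1 in hac1-2, with 0 adjusted over the list alone in both (camera adjusted p = 0.32 and 0.55). That gene, ATG13B, was 1.37-fold higher and lost its call without hac1-2 replicate 1, without any of the 3 WT libraries and on FPKM values. Flowering regulators had 2 risers and 3 fallers of 16 in hac1-1 and 2 risers and 1 faller in hac1-2 (3 and 5, and 2 and 3, adjusted over the list alone; camera adjusted p = 0.55 and 0.20). Among them FLC, the repressor of flowering, stood at 2.06 ± 1.31 CPM in WT, 6.77 ± 1.32 in hac1-1 and 7.71 ± 1.11 in hac1-2 (SD, n = 3), and FUL, which promotes flowering, fell 2.55-fold and 4.80-fold. Without hac1-1 replicate 3 or WT replicate 1, 2 flowering genes rose and 1 fell in hac1-1, and without WT replicate 3 the counts were 1 and 1. In hac1-2, 1 flowering gene rose without any of the 3 hac1-2 libraries, WT replicate 1 or WT replicate 3, and 2 and 3 fell without hac1-1 replicates 1 and 2. Of 6 measured anthocyanin and flavonoid genes 1 fell in each mutant (2 in hac1-1 and 1 in hac1-2 adjusted over the list alone; camera adjusted p = 0.17 and 0.32). In hac1-1 none fell without hac1-1 replicate 1 or 2 or WT replicate 1 or 3, and in hac1-2 the count was 2 without WT replicate 2. PAP1, an activator of anthocyanin synthesis, fell 2.12-fold in hac1-2 (edgeR adjusted p = 0.0031) and stood at 9.45 ± 2.06 CPM in hac1-1 against 14.7 ± 2.84 in WT (edgeR adjusted p = 0.094). Clock genes fell in 3 of 14 members in hac1-1 and 2 in hac1-2 (3 fell and 1 rose, and 5 fell, adjusted over the list alone; camera adjusted p = 0.14 and 0.053). CCA1 fell 1.46-fold and 1.42-fold, and RVE1 fell from 39.0 to 17.6 and 22.3 CPM. In hac1-2 the clock list passed without WT replicate 1 (0.0322) or hac1-2 replicate 1 (0.0492).

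**Figure D2:**
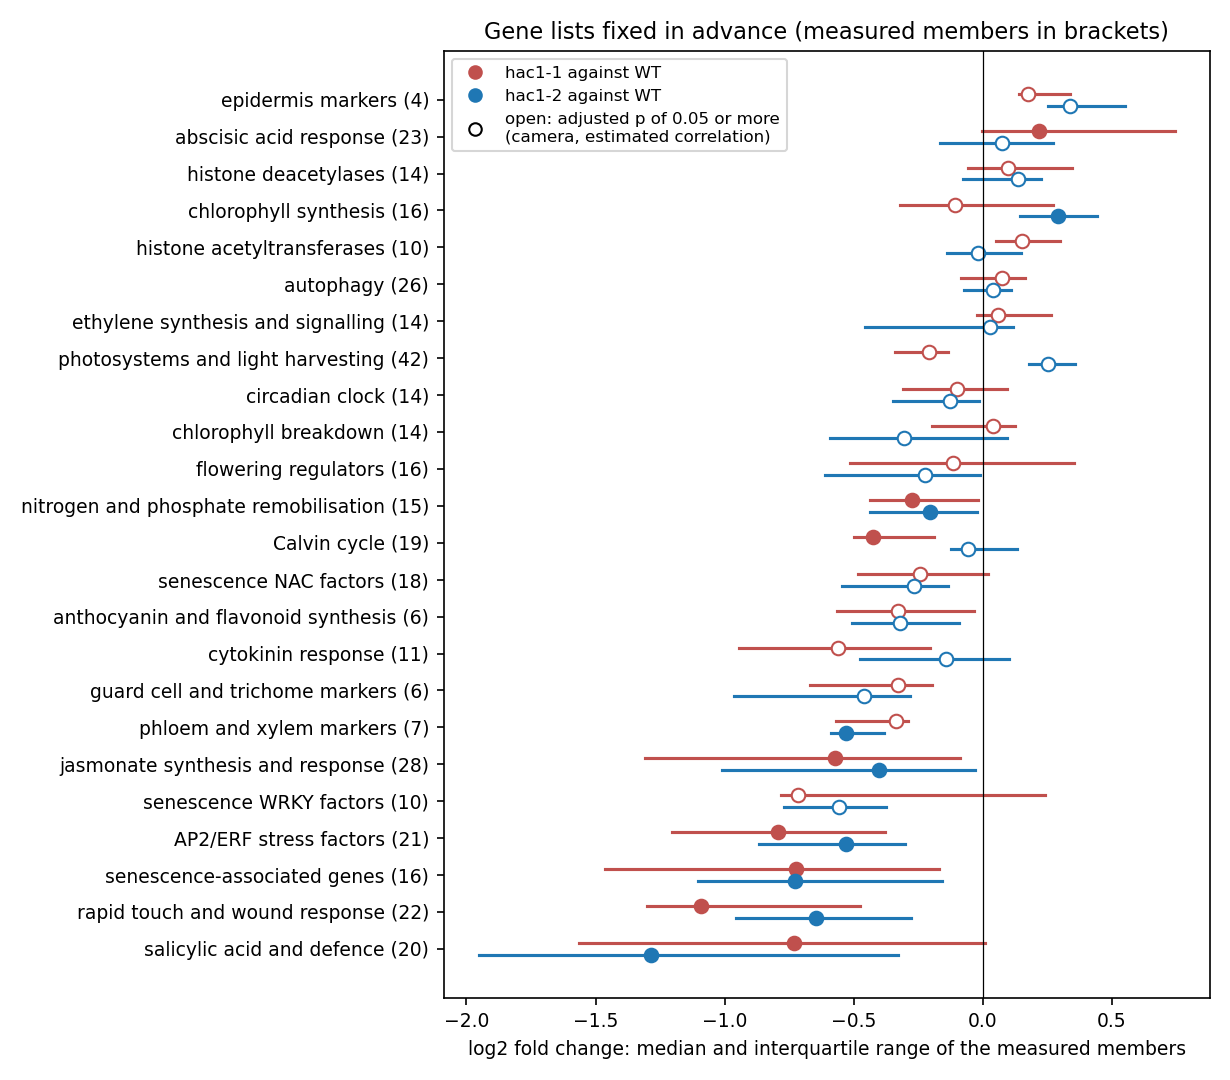
Median log2 fold change against WT (horizontal axis, points) and interquartile range (lines) of the measured members of 24 gene lists (vertical axis, number of members in brackets) in hac1-1 (red) and hac1-2 (blue); open points have a camera adjusted p of 0.05 or more with an estimated correlation. The salicylic acid, touch, senescence-associated, AP2/ERF and jasmonate lists lay below 0 in both mutants, and the photosystem list lay at -0.21 in hac1-1 and 0.25 in hac1-2.

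Genes changed in both insertion lines included a broad set that was lower and a smaller set that was higher. Among those lower were MYB15, PR1, PR5, AIG1, IGMT1, a methyltransferase gene of indole glucosinolate synthesis, and SUFE2, an iron-sulfur cluster assembly gene. IGMT1 fell 5.23-fold in hac1-1 and 6.31-fold in hac1-2, and SUFE2 4.19-fold and 6.22-fold. Among those higher were FLC, KIN1, the lipid transfer protein gene LTP3 (12.7 ± 0.908, 37.9 ± 4.39 and 47.4 ± 1.96 CPM in WT, hac1-1 and hac1-2; SD, n = 3) and the glycine-rich protein gene GRP5 (8.61, 21.1 and 37.2 CPM). AT5G46295 rose 6.41-fold and 8.59-fold. CHR42, a chromatin remodelling factor gene, rose from 1.55 to 7.09 and 6.74 CPM, and its hac1-2 call was lost on log2(FPKM + 1) values. By list, 13 touch genes, 14 jasmonate genes, 11 salicylic acid genes, 11 AP2/ERF genes and 7 senescence-associated genes were lower in both, and 5 abscisic acid genes were higher and 2 lower in both.

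In numbers, edgeR called 1077 genes in the same direction in both lines, 198 higher and 879 lower, and 4 in opposite directions. Independent lists of these sizes would share 16.6 higher and 112 lower genes. Both contrasts use the same WT libraries, which by itself raises their likeness. In 100 simulations of unchanged groups against these WT libraries, a mean of 0.04 genes was called in hac1-1 and 0.03 in hac1-2, too few calls for their overlap, which was 0, to show what the shared libraries add. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.725, against a mean of 0.489 (0.467 to 0.512) in the simulations. The covariance was 0.235 against 0.0359, a difference of 0.199. The same sign was shared by 73.4% of genes against 66.7%. The simulations drew the WT deviation from the spread between replicate libraries, which may be technical. A deviation of the WT sample as a whole is absent from them, so the simulated values can understate what the shared controls add. With 3 WT libraries the controls could not be split, so part of the excess over independent lists may come from the shared controls. The lower share of the shared genes was 81.6%, and 71.0% with library size as the only scaling. The shared count was 711 on log2(FPKM + 0.1) values.

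**Figure D3:**
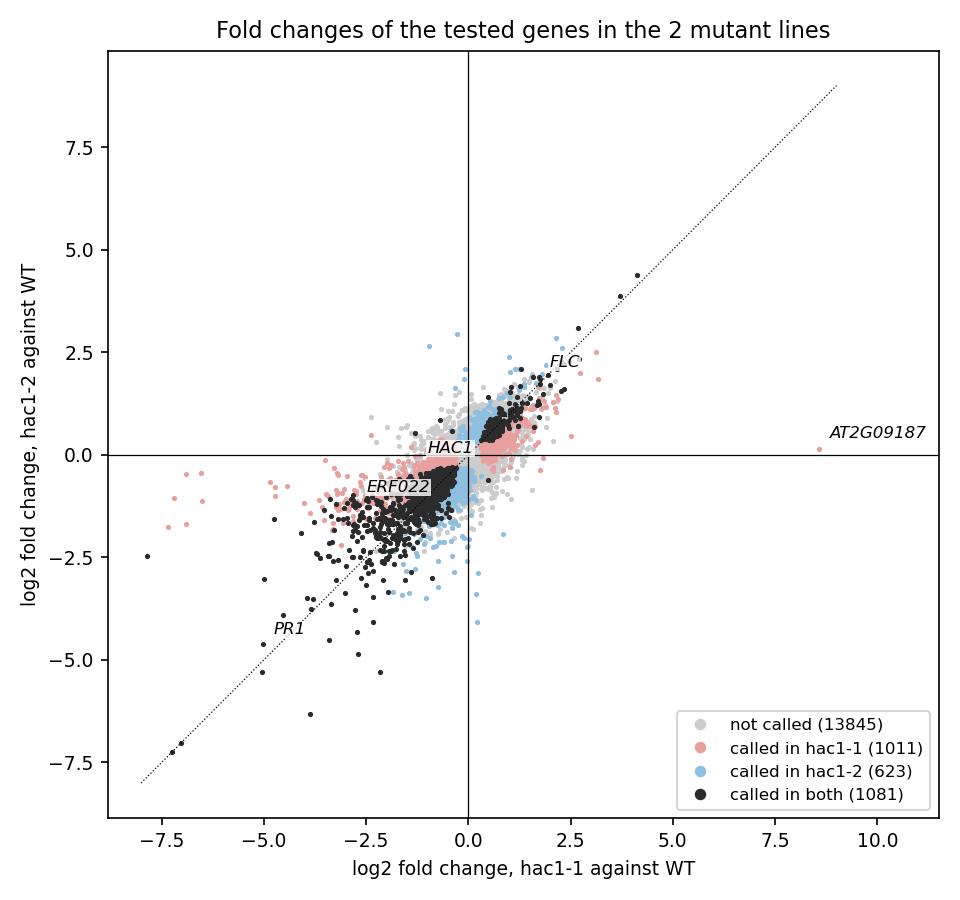
Log2 fold change of each tested gene in hac1-1 (horizontal axis) and hac1-2 (vertical axis) against WT, with genes coloured by the edgeR calls and the dotted diagonal marking equal change. Of the 1081 genes called in both, 1077 changed in the same direction and 4 in opposite directions; AT2G09187 lay far to the right with little change in hac1-2.

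The mean of both mutant lines was compared with WT as a summary of the 6 mutant libraries. PR1, MYB15 and PR2 were among the called genes, lower than WT in all 6 mutant libraries. The gene lists were not tested in this contrast. This contrast called 2300 of 16560 genes with edgeR, 619 higher and 1681 lower. The lower share was 73.1%, and it was 59.9% with library size as the only scaling and 62.1% on log2(FPKM + 1) values of genes with a mean FPKM of at least 1.

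The mutants also differed from each other, with photosynthesis and stress-factor transcripts higher in hac1-2 than in hac1-1. LHCB1.1 stood at 875 ± 52.7 CPM in hac1-1 and 1712 ± 105 CPM in hac1-2, around 1149 ± 26.3 CPM in WT (SD, n = 3). LHCB1.4 was 2.12-fold, RBCS1A 1.56-fold, ERF022 2.99-fold, DDF1 2.61-fold and SAG13 3.45-fold higher in hac1-2. Lower in hac1-2 were ICS2, an isochorismate synthase gene (6.18 ± 1.01 against 2.23 ± 0.553 CPM), and PCR1 (15.3 ± 5.12 against 5.25 ± 1.37 CPM). The gene next to the 3' end of HAC1, AT1G78995, on chromosome 1 from 29715072 to 29716255, was 3.57-fold higher in hac1-2 than in hac1-1, with 27.2 ± 5.46 CPM in WT. Between the lines edgeR called 470 genes at an adjusted p under 0.05, 308 higher and 162 lower in hac1-2. The count was 240 without hac1-1 replicate 3, 249 without hac1-2 replicate 2 and 204 without hac1-2 replicate 3. It was 721 without a filter, and 252, 241 and 260 on log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 1) values with a mean FPKM of at least 1.

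By list, 26 of 42 photosystem and light-harvesting genes were higher in hac1-2 than in hac1-1 and 0 lower (41 and 0 adjusted over the list alone), with a median difference of 0.46. Without hac1-1 replicate 3 or hac1-2 replicate 3 this count was 14, and 16 without hac1-2 replicate 2. Calvin cycle genes were higher in 8 of 19 members (14 adjusted over the list alone), with counts of 5 without hac1-1 replicate 1 or hac1-2 replicate 1, 4 without hac1-1 replicate 3 and 2 without hac1-2 replicate 3. Chlorophyll synthesis genes were higher in 5 of 16 members (8 adjusted over the list alone), and in 1 without hac1-2 replicate 3, 2 without hac1-1 replicate 3 and 3 without hac1-1 replicate 1 or hac1-2 replicate 1. AP2/ERF factors were higher in 9 of 21 (11 higher and 2 lower adjusted over the list alone), and in 5 without hac1-1 replicate 3 or hac1-2 replicate 3. Touch genes were higher in 5 of 22 members (8 higher and 1 lower adjusted over the list alone). All 5 of these lists passed camera with an estimated correlation, with adjusted p from 0.0143 to 0.0199. Jasmonate genes were higher as a list (camera adjusted p = 0.022), abscisic acid genes lower (0.0015) and chlorophyll breakdown genes lower (0.012). These 3 calls were lost with an estimated correlation (adjusted p = 0.0797, 0.0711 and 0.253).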

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

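The tests of transcription through the region of AT2G09187 and of the time of day at harvest were chosen only after the result was seen. Each of the genes and lists here is given because hac1-2 differed from hac1-1 in the edgeR test or in camera, so their effects against WT differ, and values are log2 differences of hac1-2 minus hac1-1.

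Of 133 named genes, 31 differed, 25 higher and 6 lower in hac1-2. The naming rule itself took the 6 largest rises and falls between the mutants, so these counts are partly fixed by selection. Over all 16560 tested genes, 470 differed, 308 higher and 162 lower in hac1-2. HAC1 differed by 1.05 and AT1G78995, next to it on chromosome 1, by 1.83. Differences above 1 were also found for BGAL11 (2.32), AT4G04223 (1.95, with a near-identical counted copy), BCP1 (1.86), ACA3 (1.84), SAG13 (1.79), ERF022 (1.58), DDF1 (1.39) and LHCB1.4 (1.08). Smaller positive differences were those of CYP94B3 (0.98), LHCB1.1 (0.97), RBCS2B (0.84), GRP5 (0.81), RBCS1A (0.64), PSAK (0.64), WRKY22 (0.54), ERF5 (0.52), PSAO (0.51), ACS6 (0.51), SAG14 (0.46), LHCB1.3 (0.45), PGK1 (0.45), WRKY53 (0.43) and ERF6 (0.41). Lower in hac1-2 were ICS2 (-1.45), AT4G13540 (-1.48), PCR1 (-1.53), AT3G28510 (-2.12), AT4G01390 (-3.14) and AT2G09187 (-8.43).

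Lists with a difference were photosystems and light harvesting (median 0.46), AP2/ERF stress factors (0.43), chlorophyll synthesis (0.38), Calvin cycle (0.36), touch and wound response (0.27), jasmonate (0.15), abscisic acid (-0.14) and chlorophyll breakdown (-0.16). The last 3 were lost with an estimated correlation (adjusted p = 0.0797, 0.0711 and 0.253).

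AT2G09187 held 4612 to 5296 counts per hac1-1 library, against 10 to 18 in WT and 13 to 22 in hac1-2. A general rise of pseudogene counts was argued against, since 104 tested pseudogenes had a median only 0.134 above that of protein-coding genes. Transcription running through the region stays open, although the highest of 6 neighbours reached only 0.0272% of the CPM of AT2G09187. All neighbours but AT2G09589 lie on the plus strand, AT2G09187 lies on the minus strand, and the counting strand was not given. If counting was by strand, reads from the minus strand were not counted to the plus-strand neighbours. Reads from other copies of the repeat stay open too. The summed CPM of 54 counted genes with shared sequence in hac1-1 was 21.2 times that in WT. This passed the bound set beforehand for this explanation, but only 7 of these genes had any count. Together they held 1 count in WT and 20 in hac1-1, against 14697 of AT2G09187 in hac1-1. The 95% binomial interval of the ratio (3.41 to 883) pools reads over libraries and treats them as independent. An altered or inserted copy in hac1-1 may add to the AT2G09187 counts, and no biological explanation was tested.

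Photosystem and light-harvesting genes lay 0.459 higher in hac1-2. A bias with expression level, length or GC content was argued against as the whole explanation. The 10000 matched lists had a median of 0.0956 (0.0211 to 0.173), below the 0.459 of the list. They lay above the median of all genes (-0.0051), so a smaller part of the difference may come from such a bias. A single deviating library was argued against by a lowest median of 0.419 without 1 mutant library, and shared paralog reads by a median of 0.457 over the 38 members without a near-identical copy. As a hypothesis, a difference in leaf state between the lines may underlie it, which the labels do not give and which was not tested, and a harvest that differed between the lines stays open too.

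Touch and wound genes lay lower in both mutants. The gap between the lowest WT and the highest mutant library was 0.698 against a widest range of 0.164 within a group, a bound set beforehand against handling that differed from library to library. Handling stays open all the same, because the design names 1 biological replicate, so the range within a group can lack any difference in harvest, and a harvest per genotype is confounded with genotype. A different time of day at harvest cannot be told apart from it, with 2 of 14 clock genes (CCA1 and RVE1) called in both mutants. Genotype and the labelled senescence state are open too, as untested.

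Regrouping the libraries gave 10 splits for each pair of groups, too few for a share under 0.05. Only the real split, 1 of 10, reached the real count for hac1-1 against WT (2092, highest other 0), hac1-2 against WT (1704, highest other 0) and hac1-2 against hac1-1 (470, highest other 0). Of 840 regroupings into 3 groups, 100 were used, made up of the real one and a random draw of others. The shares count the real one. Chance division of these 9 libraries was excluded, by a share under 0.05, for genes changed in both mutants (1 of 100, 1077 against a highest other of 828) and for the mean of the mutants (1 of 100, 2300 against 1714). For the gene list tests the share was under 0.05 too (2 of 100, 26 against 27). There, 1 other regrouping, which kept the WT libraries as controls and mixed the mutant lines, gave more calls than the real one. The list count therefore does not single out the real grouping of the mutants. Chance differences between plants were not tested by this, since the libraries of a genotype can be technical replicates. The highest others keep the WT libraries together, and with WT parted the highest were 32 genes in both, 218 genes for the mean and 20 list calls. Over the other regroupings drawn, the median was 12 list calls with the preset correlation. With an estimated correlation it was 0 and the highest was 16, in 1 other regrouping, as many as the real 16.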

How the results depend on the processing

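The alternative without rRNA genes was chosen only after the data were seen. Counts of called genes stayed within 1.5 times the reported count under RLE, upper-quartile and library-size scaling, DESeq2, limma-voom, the stricter filter, the groups compared alone and without rRNA genes. The count table held no plastid or mitochondrial genes, so leaving them out gave no value.

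At an adjusted p under 0.01 the counts were 1250 for hac1-1, 987 for hac1-2, 649 in both, 171 between the mutants and 1432 for the mean, and with a 2-fold minimum 758, 589, 359, 125 and 718, fewer by construction. Genes called in both in the same direction numbered 711 with log2(FPKM + 0.1). Between the mutants the count was 721 with no filter, 252 with log2(FPKM + 1), 241 with log2(FPKM + 0.1) and 260 with a mean FPKM of at least 1. The cause was not tested.

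With the replicate number as a replicate block the counts were 2511, 2054, 1286, 715 and 2721, and 27 lists were called. The numbers do not pair the libraries in the labels, although 8 of 9 libraries matched their own number best in both other groups (residual r 0.0118 to 0.144).

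Leaving out 1 library gave 1560 to 2042 genes for hac1-1, 1203 to 1974 for hac1-2, 788 to 1090 in both, 204 to 548 between the mutants, 1656 to 2505 for the mean and 25 to 28 lists. HAC1 stayed between -1.34 and -1.18 in hac1-1 and between -0.28 and -0.14 in hac1-2. Of 26 list calls 16 held with an estimated correlation. Fry, which does not compare a list with other genes, lost 0 of the 26 and gained 10. Gained in hac1-1 were the NAC, histone deacetylase, anthocyanin, clock, guard cell and epidermis lists. Gained in hac1-2 were the flowering, cytokinin, clock and guard cell lists. In simulations of unchanged groups 0 genes were shared, where means of only 0.04 and 0.03 genes were called, so this count bears on no result.

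Of 175 calls of named genes against WT, 143 held in every alternative scaling, test, filter, unit and omitted library. The stricter adjusted p and the 2-fold minimum were not applied to them. Of the calls, 28 were lost without at least 1 library, 27 under another alternative, and 0 reversed. The naming rule favoured a small adjusted p, a large change and no overlap between groups. These shares therefore do not carry over to all calls. Of all 2092 hac1-1 calls, 1484 held without WT replicate 1. Of all 1704 hac1-2 calls, 1131 held without hac1-2 replicate 2.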

Other observations

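The genes in this part were chosen only after their values were seen, and no test of an explanation was run. WRKY70, WRKY54 and RAB18 were higher in hac1-1 than in WT and lower in hac1-2 than in hac1-1. WRKY70 stood at 81.4, 125 and 62.3 CPM in WT, hac1-1 and hac1-2, and RAB18 at 211, 467 and 231 CPM. The number of senescence WRKY factors called higher in hac1-1 was 3, and 1 without WT replicate 3.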
